A study of Mus musculus with 12 samples.

How the data were processed

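RNA was sequenced from 12 tumour libraries, 3 in each of 4 treatment groups. The tumours grew from 50000 B16F10 mouse melanoma cells placed under the skin of C57Bl/6 mice. Per the labels, the mice received 25 mg/kg alisertib, 100 mg/kg navitoclax, both drugs at these doses, or vehicle, by mouth once a day for 11 days. Per the labels' protocols, ribosomal RNA was depleted from total RNA and the libraries were directional. Groups were taken from the treatment named in each sample's labels. The labels number no replicates, so libraries were numbered within each group in accession order, and a shared number pairs nothing. The labels do not say that each library came from a separate mouse, so p-values measure only the spread between these samples, which may be technical. For navitoclax 3, a part of the column name differs from the sample's title; it was matched by its library code, and the treatment written in the table, navitoclax, equals that of the label.

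The deposited table holds a normalized signal per gene and library for 50600 genes, of which 29711 had a read in some library. These are not raw counts: in every library all values (100%) were whole multiples of 1 step within 0.001, as when the authors divide gene counts by 1 size factor per library. Whole reads were recovered by dividing each column by its step. The submitters' processing notes name HISAT2 2.0.6, featureCounts, Subread 1.5.1 and DESeq2, and the builds GRCm38.p4 and mm10, with no role or order. Neither the strand setting of the counting nor the annotation release is given, so values of antisense genes and of near-identical copies (haemoglobin, Bcl2a1 and Rpl21 genes) are uncertain. Symbols and coordinates (GRCm38, counted from 1) came from GENCODE M21 by gene identifier, which matched 50376 of the 50600 genes; 91 symbols are shared by several identifiers and were kept apart by identifier.

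An edgeR test on raw counts had been planned; because the values were normalized, limma 3.58.1 in R 4.3.3 on log2(value + 2) took its place, and the count models were run on recovered reads as alternatives. Genes with a value of at least 10 in at least 3 libraries were kept (16993). One model with a mean per group was fitted to all 12 libraries, with trended, robust variance moderation. Adjusted p is Benjamini-Hochberg within each contrast, with a threshold of 0.05. The 8 contrasts were each drug arm against vehicle, the combination against each single drug, the interaction of the drugs, and the main effect of each drug (its mean effect with and without the other). Fold changes are differences of log2(value + 2) with their standard error, which understate the change of low genes. Group levels are means of the normalized values ± SD over 3 libraries.

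Before the data were examined, 24 gene lists (373 genes) were fixed, together with the contrasts and most alternatives. The lists covered drug targets, stress responses and the cell types a tumour can hold. The planned filter was that of edgeR on raw counts, and camera was planned on log2 CPM (TMM scaling). Because the values were normalized, the value filter above and log2(value + 2) took their place. Lists with at least 3 tested members (22) were tested with camera at its preset correlation of 0.01 and adjusted over the lists of a contrast; a camera call says that the members ranked higher or lower than other genes. Camera with a correlation estimated from the data, which is stricter, and fry, which asks whether the members moved one way on balance, were run beside it. For members, adjustment over the list alone was also made. The neutrophil and keratinocyte lists had 2 tested members each and no test.

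Named genes followed a rule. The first part took Aurka, Bcl2, Bcl2l1, Bcl2l2 and Cdkn1a in each arm against vehicle. The second took genes past the threshold with mean CPM (TMM scaling) of at least 2, no overlap between the libraries compared, and a gene name: the 8 with the largest change in each direction against vehicle and 5 in other contrasts. Where under 3 genes passed, the 5 with the smallest p were taken. The last part took up to 4 members of a described list, by smallest p.

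Alternatives were edgeR 4.0.16 with RLE, upper-quartile and TMM factors, DESeq2 1.42.0, limma-voom with quality weights, no filter, CPM of at least 1 in at least 3 libraries, no robust moderation, and only the compared groups in the fit. Size factors without mitochondrial, haemoglobin and the 20 largest genes, pseudocounts of 0.5 and 8, and each library left out were also run. The TMM runs, both pseudocounts, the fit without the 2 libraries rich in ribosomal RNA and the fit with the ribosomal share as a covariate were chosen after seeing the data. For the alisertib comparison, the tests were run on simulated reads of 16993 genes with 100 genes changed 2-fold and 100 changed 4-fold: limma recovered 18% and 68%, with 4 false calls among 90, edgeR 18% and 70% with 5 among 93, voom 14% and 71% with 2 among 87, and DESeq2 36% and 85% with 39 false calls among 160. In the navitoclax comparison of the same simulated reads, where no gene was changed, DESeq2 made 23 calls and the other tools 0. Each of the 3 list tests called the 1 shifted list of 22 and no other. The simulated genes varied independently, so this does not measure false list calls where members vary together. Nor does it measure false gene calls where whole libraries deviate, since no simulated library did. Other splits of the libraries and the effect of sharing the 3 vehicle libraries between contrasts were also computed.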

Results

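Gene transcripts were measured in B16F10 tumours given vehicle, alisertib, navitoclax or both drugs (3 libraries each). Alisertib inhibits Aurora kinase A, encoded by Aurka. Navitoclax inhibits the survival proteins BCL-2, BCL-xL and BCL-w, encoded by Bcl2, Bcl2l1 and Bcl2l2. Each library held 26.8 to 36.7 M reads (M, mega). Of these, 2 ribosomal RNA loci took 63.3% in vehicle 2 (95% interval 63.2 to 63.3) and 73.7% in combination 3 (73.7 to 73.7), against 13.8 to 35.4% in the other 10 libraries. These loci were Gm26917 (chr17:39843013-39846341, plus strand) and Gm42418 (chr17:39846958-39848788, plus strand, GRCm38). The end of the small-subunit ribosomal RNA was found in Gm42418 but not in Gm26917. Gm26917 took 57.7% of the reads in vehicle 2 and 68.3% in combination 3, and its ribosomal origin was not shown here. The ribosomal share below means both loci together. Reads from other genes numbered 9.86 M in vehicle 2 and 7.08 M in combination 3, against 21.9 to 27.6 M in the rest. A value of 3 reads was 7.35 in vehicle 2, 10.9 in combination 3 and from 2.29 upwards elsewhere. These intervals and floors cover counting error only.

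**Figure D1:**
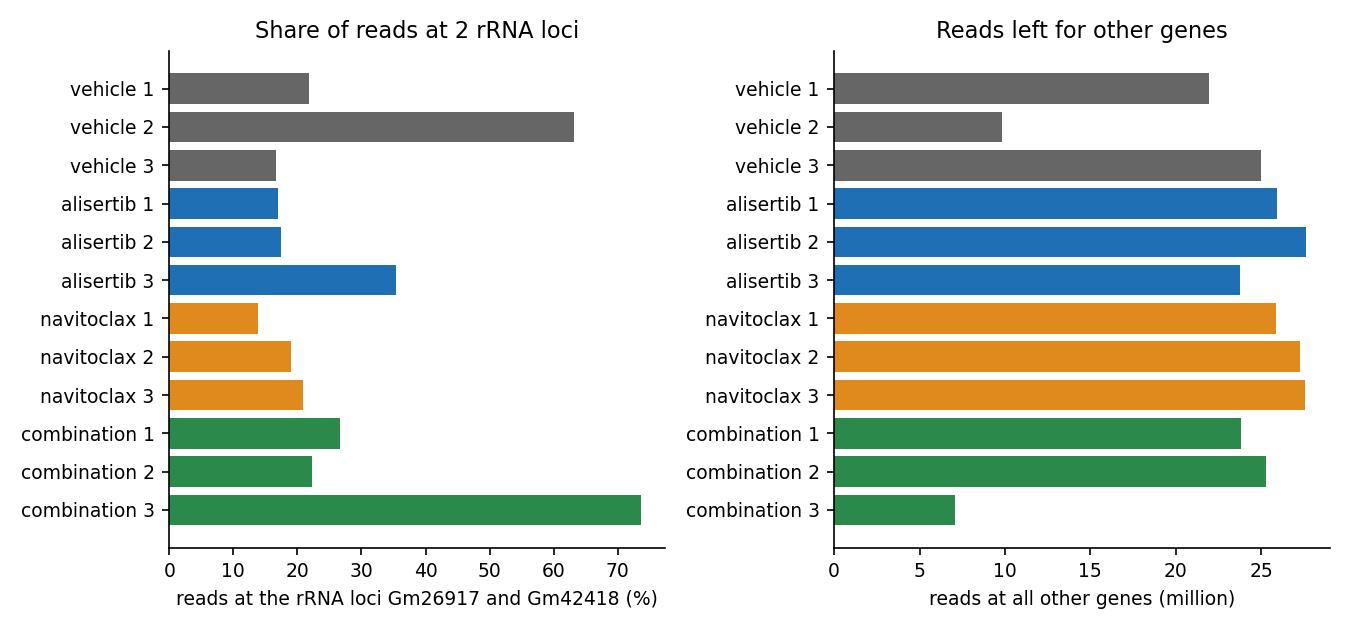
Reads per library, split into the 2 ribosomal RNA loci and all other genes. Vehicle 2 and combination 3 carried the fewest reads outside these loci.

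The first principal component (39.0% of the variance) set apart vehicle 2 (78.9) and combination 3 (118) from the other libraries (−35.4 to 10.9). The second and the next component held 19.5% and 12.3%. Replicates correlated with r of 0.934 to 0.985, and no 2 replicates of a group were duplicates.

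The alisertib arm asks what inhibition of Aurora kinase A does to tumour RNA. Cdkn1a (ENSMUSG00000023067.13, chr17:29090976-29100727, plus strand), which encodes the cell cycle inhibitor p21, rose by 1.32 ± 0.20 log2 (adjusted p = 0.0127). Its level was 4307 ± 919 with vehicle and 10572 ± 366 with alisertib (n = 3 each). Other p53 target genes rose with it. Zmat3 (ENSMUSG00000027663.12, chr3:32334792-32366014, minus strand) rose by 1.24 ± 0.13 (adjusted p = 0.00141) and Ccng1, cyclin G1, by 1.54 ± 0.19 (adjusted p = 0.00376). Trp53inp1 (ENSMUSG00000028211.11, chr4:11156431-11174379, plus strand) rose by 2.32 ± 0.25 (adjusted p = 0.00141). Hspa5 (ENSMUSG00000026864.13, chr2:34771970-34777547, plus strand), the endoplasmic reticulum chaperone BiP, fell by 1.04 ± 0.13 (adjusted p = 0.00314). Chac1 (ENSMUSG00000027313.3, chr2:119351229-119354381, plus strand), a glutathione-degrading enzyme of the integrated stress response, fell from 685 ± 16.6 to 83.8 ± 5.63 (adjusted p = 0.00612). In all, 148 of 16993 genes passed, 94 higher and 54 lower. Aurka itself (ENSMUSG00000027496.15, chr2:172356190-172370535, minus strand) did not pass (−0.24 ± 0.18, adjusted p = 0.593), with 1212 ± 227 and 1028 ± 212.

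Of the genes taken by the rule for size of change, the largest rise was of Cpz (ENSMUSG00000036596.6, chr5:35502218-35525698, minus strand), carboxypeptidase Z (3.21 ± 0.31, adjusted p = 0.000927). Svop (ENSMUSG00000042078.14, chr5:114026910-114091570, minus strand), a relative of synaptic vesicle transporters, rose by 3.17 ± 0.37 (adjusted p = 0.00243). Eda2r, a receptor of the TNF receptor family, rose by 2.87 ± 0.49 (adjusted p = 0.022) and Ccl6, a chemokine, by 2.66 ± 0.52 (adjusted p = 0.0419). Celf5 (2.65 ± 0.29), Pqlc3 (2.43 ± 0.33) and Slc2a9, a urate transporter (2.21 ± 0.20), also rose. Fgf21 (ENSMUSG00000030827.5, chr7:45613886-45615490, minus strand), a hormone of the FGF family, had the largest fall (−6.59 ± 0.61, 668 ± 287 to 4.62 ± 1.78, adjusted p = 0.000851). Cdsn, corneodesmosin (−5.36 ± 0.68), and P2rx3, an ATP-gated channel (−5.17 ± 0.66), followed. Sspo (ENSMUSG00000029797.13, chr6:48448229-48501250, plus strand), SCO-spondin, fell by 4.92 ± 0.41. Avil (ENSMUSG00000025432.11, chr10:127000709-127020994, plus strand), the actin-binding protein advillin, fell by 3.60 ± 0.32. Tenm4, a teneurin (−3.40 ± 0.35), and Pycr1, an enzyme of proline synthesis (−2.96 ± 0.49, adjusted p = 0.0198), fell as well.

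Of 22 lists, 9 passed. The p53 targets ranked higher, with 11 of 17 risen, 0 fallen and 6 not passing (13 risen over the list alone). Their median was 1.09 (adjusted p = 6.62e-21, and 0.00132 with an estimated correlation). Fas, a death receptor chosen after its values were seen, rose by 3.61 ± 0.64 (adjusted p = 0.0265). The unfolded protein and integrated stress response list ranked lower (median −0.75, adjusted p = 4.04e-08, but adjusted p = 0.165 with an estimated correlation). In it Hspa5, Chac1 and the pseudokinase Trib3 (−2.74 ± 0.51, adjusted p = 0.0348) fell, 0 rose and 13 of 16 did not pass (1 risen and 8 fallen over the list alone). In the DNA replication list (20) and the mitosis list (22) 0 members passed, also over the list alone. DNA replication had a median of −0.43 (adjusted p = 1.27e-05, but adjusted p = 0.423 with an estimated correlation), with Mcm5, a helicase subunit, at −0.51 ± 0.14 (adjusted p = 0.148). Mitosis had −0.18 (adjusted p = 0.00678, but adjusted p = 0.72 with an estimated correlation), with the proliferation marker Mki67 at −0.52 ± 0.16 (adjusted p = 0.202).

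No member passed in the other 5 lists called. Senescence-associated secretory factors had a median of 0.88 (14 of 20 positive, adjusted p = 0.009, but adjusted p = 0.507 with an estimated correlation). The BCL2 family, which shares Bax, Bbc3 and Pmaip1 with the p53 list, had 0.30 (2 of 15 higher over the list alone, adjusted p = 0.0475, but adjusted p = 0.374 with an estimated correlation). Bcl2l1, which encodes BCL-xL, stood at 0.69 ± 0.19 (adjusted p = 0.156) and the death effector Bax at 0.60 ± 0.16 (adjusted p = 0.135). Bcl2 was at −0.01 ± 0.17 (adjusted p = 0.989) and Bcl2l2 at −0.02 ± 0.15 (adjusted p = 0.966). Markers of other cells stood beside these. Macrophage and monocyte genes had a median of 1.27 (15 of 15 positive, 4 higher over the list alone, adjusted p = 1.27e-05, but adjusted p = 0.466 with an estimated correlation). Among them were Mrc1 at 1.98 ± 0.52 (adjusted p = 0.131) and Cd68 at 2.27 ± 0.61 (adjusted p = 0.134). Erythroid genes had −2.40 (6 of 7 lower over the list alone, adjusted p = 7.95e-05, but adjusted p = 0.423 with an estimated correlation). Melanocyte differentiation genes had 0.41 (1 of 16 higher over the list alone, adjusted p = 0.000145, but adjusted p = 0.507 with an estimated correlation). Mc1r, the melanocortin receptor, was at 0.86 ± 0.22 (adjusted p = 0.122). The neutrophil and keratinocyte lists, untested, had medians of 0.96 and −0.56.

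The 148 genes became 56 without vehicle 1, 80 without vehicle 2, and 49, 54 and 67 without alisertib 1, 2 and 3. They were 625 with DESeq2, 1224 with quality weights, 770 with the ribosomal share as a covariate and 90 with only the compared groups in the fit. The balance of directions moved with them, from 94 higher and 54 lower to 333 and 292, 626 and 598, 384 and 386, and 44 and 46. Cdkn1a no longer passed without vehicle 1 (adjusted p = 0.0511) or alisertib 1, 2 or 3 (0.0765, 0.0644, 0.0548). Nor did Eda2r without vehicle 1 or 2 or any alisertib library (up to 0.126), or Pycr1 without vehicle 1 or 3 or any alisertib library (up to 0.112). Ccl6 was lost without each library but navitoclax 2 and combination 3 (up to 0.167), and Trib3 without each but navitoclax 1 and 2 and combination 3 (up to 0.137). The mitosis list was lost without vehicle 1 (0.107) or alisertib 2 (0.0654), and secretory factors without vehicle 1 (0.152) or alisertib 2 (0.177). The BCL2 family was lost without vehicle 1 or 3, alisertib 3 or combination 1 (0.0547 to 0.148).

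**Figure D2:**
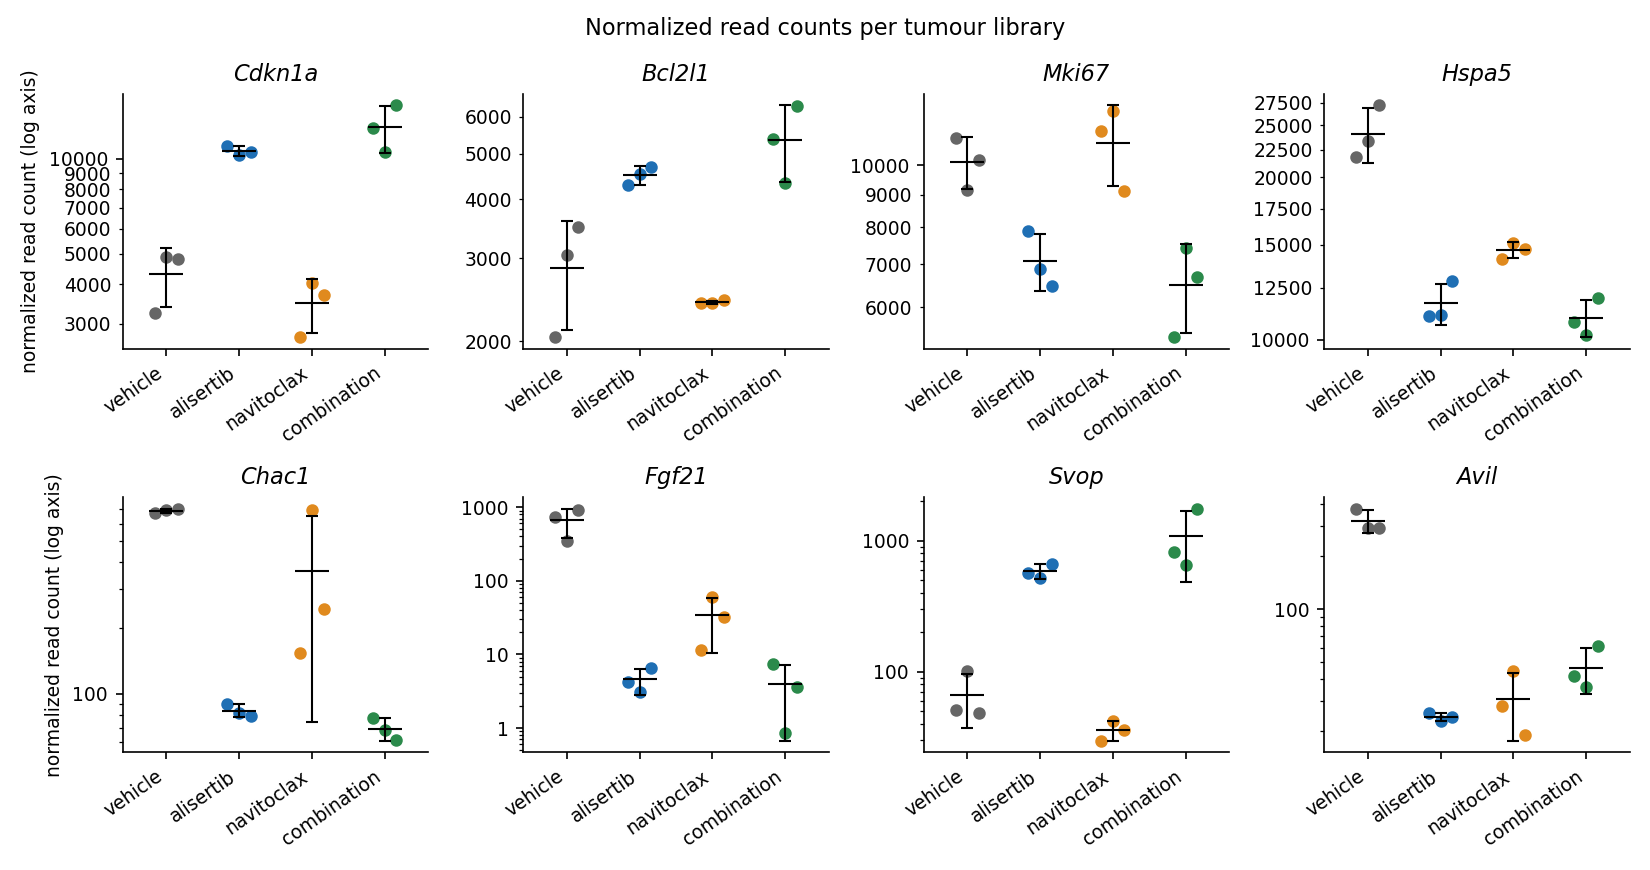
Normalized level of 8 named genes in each library, with mean and SD per group, on a log axis. Each point is 1 library, and Fgf21 in the arms with alisertib lies near the 3-read floor.

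The navitoclax arm asks what inhibition of the BCL-2 proteins alone does. Only 11 genes passed, all lower than in vehicle tumours. Fgf21 fell by 4.34 ± 0.61 (668 ± 287 to 34.7 ± 24.3, n = 3 each, adjusted p = 0.0334) and Sspo by 4.22 ± 0.41 (932 ± 213 to 52.3 ± 25.6, adjusted p = 0.00422). Avil was lower by −3.37 ± 0.32 (319 ± 48.0 to 30.5 ± 12.8, adjusted p = 0.00422). Abca4 (ENSMUSG00000028125.14, chr3:122044443-122180123, plus strand), a transporter known from the retina, was lower by −3.07 ± 0.38 (adjusted p = 0.0218). Tenm4 (ENSMUSG00000048078.16, chr7:96171246-96911093, plus strand) fell by 2.50 ± 0.35 (adjusted p = 0.0334). Plekha6 (ENSMUSG00000041757.16, chr1:133164210-133303435, plus strand) fell by 2.17 ± 0.32 (adjusted p = 0.0393). The transcripts of the drug's targets did not pass: Bcl2 −0.31 ± 0.17 (adjusted p = 0.704), Bcl2l1 −0.20 ± 0.19 (adjusted p = 0.721) and Bcl2l2 0.17 ± 0.15 (adjusted p = 0.716). Nor did Cdkn1a (−0.30 ± 0.20, adjusted p = 0.704) or Aurka (0.08 ± 0.18, adjusted p = 0.855).

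No member of any list passed in this arm, while 10 lists passed as sets, each with adjusted p = 0.559 with an estimated correlation. Mitosis (median 0.28, 20 of 22 positive, adjusted p = 0.000182) and DNA replication (0.23, adjusted p = 0.000564) ranked higher. Plk1, a mitotic kinase, was at 0.50 ± 0.19 (adjusted p = 0.704). The stress response list ranked lower (−0.47, 2 lower over the list alone, adjusted p = 5.27e-05), with Hspa5 at −0.71 ± 0.13 (adjusted p = 0.137), as did the hypoxia list (−0.38, adjusted p = 0.000939). Interferon response (0.79, 21 of 21 positive, adjusted p = 9.76e-05) and macrophage genes (0.66, adjusted p = 0.00139) ranked higher. So did melanocyte differentiation (0.39, 1 higher over the list alone, adjusted p = 9.76e-05) and skeletal muscle genes (2.89, 16 of 16 positive, adjusted p = 5.69e-05). Erythroid (−1.31, adjusted p = 0.00114) and adipocyte genes (−2.07, adjusted p = 0.00114) ranked lower. The p53 list had a median of 0.02 (adjusted p = 0.937).

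The 11 genes became 2, 3 and 2 without vehicle 1, 2 and 3, and 2, 3 and 3 without alisertib 1, 2 and 3. They were 2 without navitoclax 1 or 3 and 20 without navitoclax 2. Other settings gave 76 (DESeq2), 37 (quality weights), 21 and 3 (pseudocounts of 8 and 0.5), 4 (CPM filter) and 0 (only the compared groups). Fgf21 and Tenm4 were lost without any vehicle or alisertib library or navitoclax 1 or 3 (adjusted p up to 0.291 and 0.294). Abca4 was lost without vehicle 1 or 3, any alisertib library or navitoclax 1 or 3 (up to 0.147), and Plekha6 without each library but combination 2 and 3 (up to 0.32). Of the lists, interferon response was lost without navitoclax 3 (0.908), and muscle (0.676) and hypoxia (0.143) without navitoclax 1. Macrophage genes were lost without vehicle 1 (0.246), navitoclax 1 (0.0599) or navitoclax 3 (0.0831), erythroid genes without navitoclax 2 (0.0525) and adipocyte genes without vehicle 3 (0.134).

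The combination arm asks what both drugs do against vehicle. Cdkn1a rose by 1.56 ± 0.20 (12604 ± 2144 against 4307 ± 919, n = 3 each, adjusted p = 0.00282). Zmat3 rose by 1.41 ± 0.13 (adjusted p = 0.000582), Trp53inp1 by 2.33 ± 0.25 (adjusted p = 0.00106) and Ccng1 by 1.78 ± 0.19 (adjusted p = 0.00114). Aen, an exonuclease induced by p53, rose by 1.05 ± 0.14 (adjusted p = 0.00259). Bcl2l1 (ENSMUSG00000007659.18, chr2:152780668-152831728, minus strand), whose protein navitoclax inhibits, rose by 0.92 ± 0.19 (5354 ± 995 against 2858 ± 746, adjusted p = 0.0346) and Bax by 0.75 ± 0.16 (adjusted p = 0.0376). Hspa5 fell by 1.13 ± 0.13 (adjusted p = 0.00129), Chac1 by 3.28 ± 0.42 (adjusted p = 0.00247) and Trib3 by 3.45 ± 0.51 (adjusted p = 0.00607). In all, 431 genes passed, 235 higher and 196 lower. Aurka (−0.18 ± 0.18, adjusted p = 0.699), Bcl2 (−0.02 ± 0.17, adjusted p = 0.973) and Bcl2l2 (0.16 ± 0.15, adjusted p = 0.693) did not pass.

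By the rule, the largest rises were of Svop (3.92 ± 0.37, adjusted p = 0.000582) and Plcd4, a phospholipase C (3.89 ± 0.74, adjusted p = 0.0222). Cpz (3.36 ± 0.31, adjusted p = 0.000508), Wfdc17 (3.30 ± 0.68, adjusted p = 0.0323) and Wfdc3 (3.25 ± 0.74, adjusted p = 0.0451) followed. Ctss, the lysosomal protease cathepsin S, rose by 2.82 ± 0.55 (adjusted p = 0.0238) and Celf5 by 2.75 ± 0.29 (adjusted p = 0.00102). Csf2rb2, a receptor subunit for interleukin 3, rose by 2.74 ± 0.51 (adjusted p = 0.0201). By the rule, the largest falls were of Fgf21 (−6.87 ± 0.61, adjusted p = 0.000508), P2rx3 (−5.90 ± 0.66, adjusted p = 0.00125) and Cdsn (−5.87 ± 0.68, adjusted p = 0.00151). Sspo (−4.90 ± 0.41, adjusted p = 0.000508), Tenm4 (−3.93 ± 0.35, adjusted p = 0.000508) and Pycr1 (−3.43 ± 0.49, adjusted p = 0.00515) fell as well. Fgf21 (3.96 ± 3.28) and P2rx3 (5.99 ± 6.01) rested on a few reads here, so their fold depends on the pseudocount.

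Against vehicle, 87 genes passed as higher in both the alisertib and the combination arm and 53 as lower in both, where independent sets would share 1.30 and 0.623. The contrasts share their vehicle libraries. In 100 simulations with such sharing alone, fold changes correlated at 0.50 (0.72 in the data) and no gene passed in both. With 3 vehicle libraries the controls cannot be split, so a part of the shared calls may come from them.

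**Figure D3:**
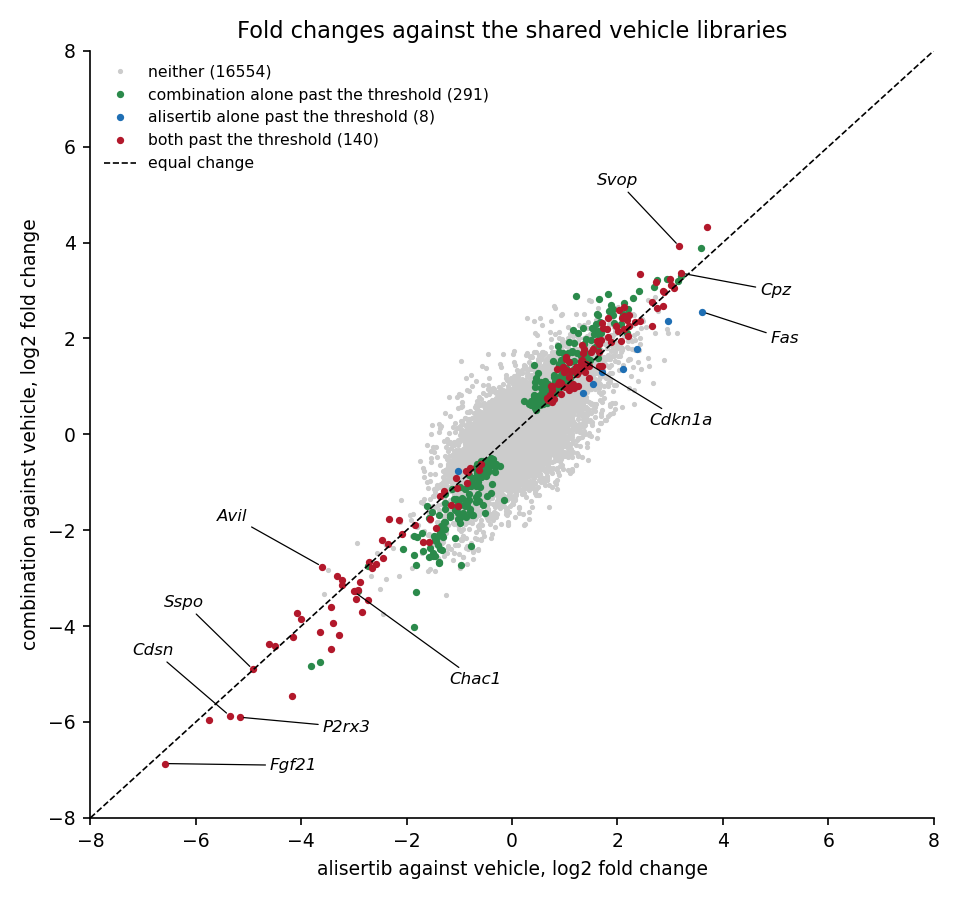
Log2 fold change against vehicle of each tested gene, alisertib on one axis and the combination on the other, coloured by the arms in which it passed. Both axes share the 3 vehicle libraries, which alone gives a positive correlation.

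With both drugs 10 lists passed. The p53 targets ranked higher, with 12 of 17 risen, 0 fallen and 5 not passing (15 risen over the list alone). Their median was 1.18 (adjusted p = 2.22e-20, and 0.00144 with an estimated correlation). The stress response list had a median of −1.03 (adjusted p = 3.03e-09, but adjusted p = 0.119 with an estimated correlation). In it 5 of 16 fell, among them Hspa5, Chac1 and Trib3, and 10 did not pass (11 lower over the list alone). Sesn2, also a p53 target, rose by 1.15 ± 0.21 (adjusted p = 0.018). In the BCL2 family 2 of 15 rose, Bcl2l1 and Bax, the latter also in the p53 list (4 over the list alone), with a median of 0.19 (adjusted p = 0.00573, but adjusted p = 0.128 with an estimated correlation). Mitosis (−0.36, 2 of 22 lower over the list alone, adjusted p = 4.65e-05) and DNA replication (−0.32, adjusted p = 0.000116) ranked lower with no member passing. For both, adjusted p = 0.328 with an estimated correlation. Mki67 was at −0.65 ± 0.16 (adjusted p = 0.0606). Hypoxia genes ranked lower (−0.67, 10 of 16 over the list alone, adjusted p = 2.7e-07, but adjusted p = 0.328 with an estimated correlation). The glucose transporter Slc2a1 was at −1.17 ± 0.29 (adjusted p = 0.06).

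Among the lists of other cells, macrophage genes ranked higher (1.78, 7 higher over the list alone, adjusted p = 1.16e-05, but adjusted p = 0.328 with an estimated correlation). Of these Ms4a7, a macrophage membrane protein, rose by 2.49 ± 0.51 (adjusted p = 0.0322). MHC class II genes (1.25, 8 of 8 positive, adjusted p = 0.0443, but adjusted p = 0.635 with an estimated correlation) ranked higher. Melanocyte differentiation genes did so too (0.32, 4 higher over the list alone, adjusted p = 0.00151, but adjusted p = 0.442 with an estimated correlation). Erythroid genes ranked lower (−2.96, 7 of 7 over the list alone, adjusted p = 5.91e-06, but adjusted p = 0.284 with an estimated correlation). Cd22, a B cell receptor, rose by 2.69 ± 0.47 (adjusted p = 0.0151) in a list that did not pass (adjusted p = 0.119).

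The 431 genes became 111, 276 and 286 without vehicle 1, 2 and 3, 251 and 283 without alisertib 1 and 2, and 215 and 200 without combination 1 and 2. DESeq2 gave 1184, quality weights 2104, the covariate 2028 and only the compared groups 66. The balance of 235 higher and 196 lower turned with the covariate (982 and 1046) and without combination 1 (103 and 112), and was even with only the compared groups (33 and 33). By adjusted p, Bcl2l1 was lost without each library but vehicle 3, navitoclax 2 and combination 2 (up to 0.105). Bax was lost without any vehicle or combination library, alisertib 2 or navitoclax 2 (up to 0.149). Wfdc3 was lost without each library but vehicle 3 (up to 0.155), and Wfdc17 without vehicle 1 or 2, alisertib 3 or combination 2 or 3 (up to 0.135). Plcd4 was lost without vehicle 1 or 2 or any combination library (up to 0.0868), and Csf2rb2 without vehicle 1 or any combination library (up to 0.0856). Ctss was lost without vehicle 1 or 3 or combination 2 or 3 (up to 0.0982), and Ms4a7 without vehicle 1 or 2, alisertib 1 or combination 2 or 3 (up to 0.124). Cd22 was lost without vehicle 1 (0.0746) or combination 2 (0.0546), and Sesn2 without vehicle 1 (0.0868) or combination 1 (0.0619). MHC class II was lost without vehicle 1 (0.17), alisertib 3 (0.0512), combination 2 (0.32) or combination 3 (0.0512), and melanocyte differentiation without vehicle 2 (0.0665).

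Adding navitoclax to alisertib is tested by the combination against alisertib alone. In limma, 0 genes passed, with 596 at an unadjusted p under 0.05, and edgeR, DESeq2 and voom with quality weights also gave 0. The combination stood above alisertib alone by 0.24 for Cdkn1a (95% interval −0.20 to 0.68), 0.23 for Bcl2l1 (−0.19 to 0.66) and 0.75 for Svop (−0.06 to 1.56). Chac1 was at −0.28 (−1.19 to 0.64) and Fgf21 at −0.28 (−1.62 to 1.05). Over the 439 genes called in either arm the interval reached a median of 0.60 to each side. This is no bound, since for single genes such as Svop and Fgf21 larger differences are not excluded either. For 60 of the 439 genes the interval, unadjusted for their number, excluded 0, as for Avil (0.84, 0.15 to 1.54). Over all 16993 genes, 596 had an unadjusted p under 0.05. The 439 were called with the same alisertib and combination libraries, which can favour such intervals, so the 60 are no evidence of a difference. The genes with the smallest p did not pass (adjusted p = 0.681). They were Cyr61, a matricellular protein (−0.92 ± 0.22, from 773 ± 240 to 401 ± 70.0), Kdelr3, a receptor that returns proteins to the endoplasmic reticulum (−0.92 ± 0.23), and Abcc10 (0.48 ± 0.13). The antisense gene Snhg7os (1.02 ± 0.26) and Rpl21, a ribosomal protein gene with near-identical copies (−0.69 ± 0.18), are uncertain.

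Of the lists, 5 passed with no member passing, also over the list alone, and none with an estimated correlation. MHC class I genes (median 0.90, 11 of 13 positive, adjusted p = 0.00513, but adjusted p = 0.656 with an estimated correlation) ranked higher with both drugs. So did MHC class II genes (1.38, 8 of 8 positive, adjusted p = 0.0206, but adjusted p = 0.669 with an estimated correlation). T and NK cell markers ranked higher too (0.33, 6 of 6 positive, adjusted p = 0.0482, but adjusted p = 0.656 with an estimated correlation). Tap2, a peptide transporter, was at 0.99 ± 0.50 and perforin, Prf1, at 1.90 ± 0.71. Hypoxia genes (−0.59, 0 of 16 positive, adjusted p = 1.29e-06) and endothelial markers (−0.40, adjusted p = 0.00848) ranked lower, each with adjusted p = 0.656 with an estimated correlation. Bnip3 was at −1.28 ± 0.41 and Pecam1 at −0.98 ± 0.39. The 5 lists became 2 without combination 2 and 9 without combination 3. Without combination 2, MHC class I (adjusted p = 0.322), MHC class II (0.355), T and NK cells (0.355) and endothelial markers (0.322) were lost. MHC class II was also lost without alisertib 1 (0.0811) or 3 (0.109). T and NK cell markers were also lost without vehicle 1, 2 or 3 (0.0592, 0.0843, 0.0619) or alisertib 1 (0.121) or 3 (0.149).

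Adding alisertib to navitoclax is tested by the combination against navitoclax alone, where 202 genes passed, 164 higher and 38 lower. Cdkn1a rose by 1.86 ± 0.20 (12604 ± 2144 against 3488 ± 687, n = 3 each, adjusted p = 0.00157). Mdm2, the negative regulator of p53, rose by 1.39 ± 0.16 (adjusted p = 0.00224), Zmat3 by 1.39 ± 0.13 (adjusted p = 0.00101) and Ccng1 by 1.70 ± 0.19 (adjusted p = 0.00224). The BCL2 family members Bcl2l1 (1.13 ± 0.19, adjusted p = 0.0208), Bax (0.99 ± 0.16, adjusted p = 0.0161) and Bbc3, the death activator PUMA (1.86 ± 0.31, adjusted p = 0.0189), rose. Top2a (ENSMUSG00000020914.17, chr11:98992943-99024189, minus strand), a topoisomerase of dividing cells, fell by 1.02 ± 0.20 (adjusted p = 0.0409). The spindle checkpoint kinase Bub1b fell by 0.71 ± 0.14 (adjusted p = 0.0351) and Mcm5 by 0.72 ± 0.14 (adjusted p = 0.0388). Tyms, thymidylate synthase, fell by 1.05 ± 0.21 (adjusted p = 0.0425) and Pola1, a DNA polymerase subunit, by 0.90 ± 0.18 (adjusted p = 0.0384). By the rule, the largest rises were of Svop (4.72 ± 0.37), Cpz (4.11 ± 0.31), Plcd4 (3.91 ± 0.74), Timp4, a metalloproteinase inhibitor (3.69 ± 0.73), and Mylk3 (2.87 ± 0.52). By the rule, the largest falls were of Chac1 (−2.07 ± 0.42), Hoxb9 (−1.57 ± 0.30), Cyr61 (−1.36 ± 0.22), Nt5dc2 (−1.32 ± 0.20) and E2f8, an atypical E2F factor (−1.31 ± 0.25).

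In this contrast 9 lists passed. The p53 targets ranked higher, with 10 of 17 risen and 0 fallen (15 risen over the list alone). Their median was 1.39 (adjusted p = 3.07e-18, and 0.00215 with an estimated correlation). Mitosis ranked lower, with 2 of 22 fallen and 16 over the list alone (−0.62, adjusted p = 5.81e-10, but adjusted p = 0.237 with an estimated correlation). In DNA replication 3 of 20 fell, and 13 over the list alone (−0.55, adjusted p = 1.14e-08, but adjusted p = 0.237 with an estimated correlation). The BCL2 family ranked higher, with 3 of 15 risen, of which Bax and Bbc3 are also in the p53 list (0.29, adjusted p = 0.0106, but adjusted p = 0.227 with an estimated correlation). The stress response ranked lower (−0.71, adjusted p = 0.00146, but adjusted p = 0.409 with an estimated correlation). In it Chac1 fell, Sesn2 rose (1.38 ± 0.21, adjusted p = 0.0115) and 14 of 16 did not pass. With no member passing, macrophage genes ranked higher (0.71, adjusted p = 0.0491). Erythroid (−1.56, adjusted p = 0.0272), skeletal muscle (−2.89, adjusted p = 0.00445) and hypoxia genes (−0.46, adjusted p = 0.0103) ranked lower. For these 4 lists, adjusted p = 0.758 with an estimated correlation.

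The 202 genes became 134 without vehicle 3, 98, 99 and 112 without alisertib 1 to 3, 70, 77 and 73 without navitoclax 1 to 3, and 53 and 82 without combination 1 and 3. Other settings gave 1008 (DESeq2), 1623 (quality weights), 630 (covariate), 358 (without the 2 libraries rich in ribosomal RNA), 117 (no filter) and 13 (only the compared groups). The share of higher genes was not stable: 164 higher and 38 lower became 630 and 378 with DESeq2, 911 and 712 with quality weights, 363 and 267 with the covariate, and 52 and 1 without combination 1. By adjusted p, Top2a, Tyms, Mcm5, Pola1 and Bub1b were lost without each library but vehicle 2 and combination 2 (up to 0.155, 0.162, 0.16, 0.15 and 0.149). Hoxb9 was lost without each but vehicle 2 and navitoclax 1 (up to 0.144), and Chac1 without each but vehicle 2 and navitoclax 1 and 2 (up to 0.131). Plcd4 was lost without each but vehicle 2, navitoclax 1 and combination 2 (up to 0.138), and Timp4 without each but vehicle 2, alisertib 3 and combination 2 (up to 0.155). E2f8 was lost without any alisertib or navitoclax library or combination 1 or 3 (up to 0.142). Mylk3 was lost without alisertib 1 or 2, navitoclax 1 or 2 or combination 1 or 3 (up to 0.112). Cyr61 was lost without navitoclax 2 or 3 or combination 1 (up to 0.0885). Nt5dc2 and Bax were lost without navitoclax 1 or 2 or combination 1 (up to 0.0682 and 0.095). Bbc3 was lost without any navitoclax library or combination 1 (up to 0.0887), Bcl2l1 without these or combination 3 (up to 0.103), and Sesn2 without combination 1 (0.0652). Macrophage genes were lost without vehicle 2 (0.055) or 3 (0.0529), alisertib 3 (0.0598), navitoclax 2 (0.762) or combination 2 (0.315). Erythroid genes were lost without navitoclax 1 (0.163) or combination 1 (0.107) or 2 (0.0545), muscle without navitoclax 1 (0.692) or combination 1 (0.0818), and hypoxia without navitoclax 2 (0.0809) or combination 2 (0.315).

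**Figure D4:**
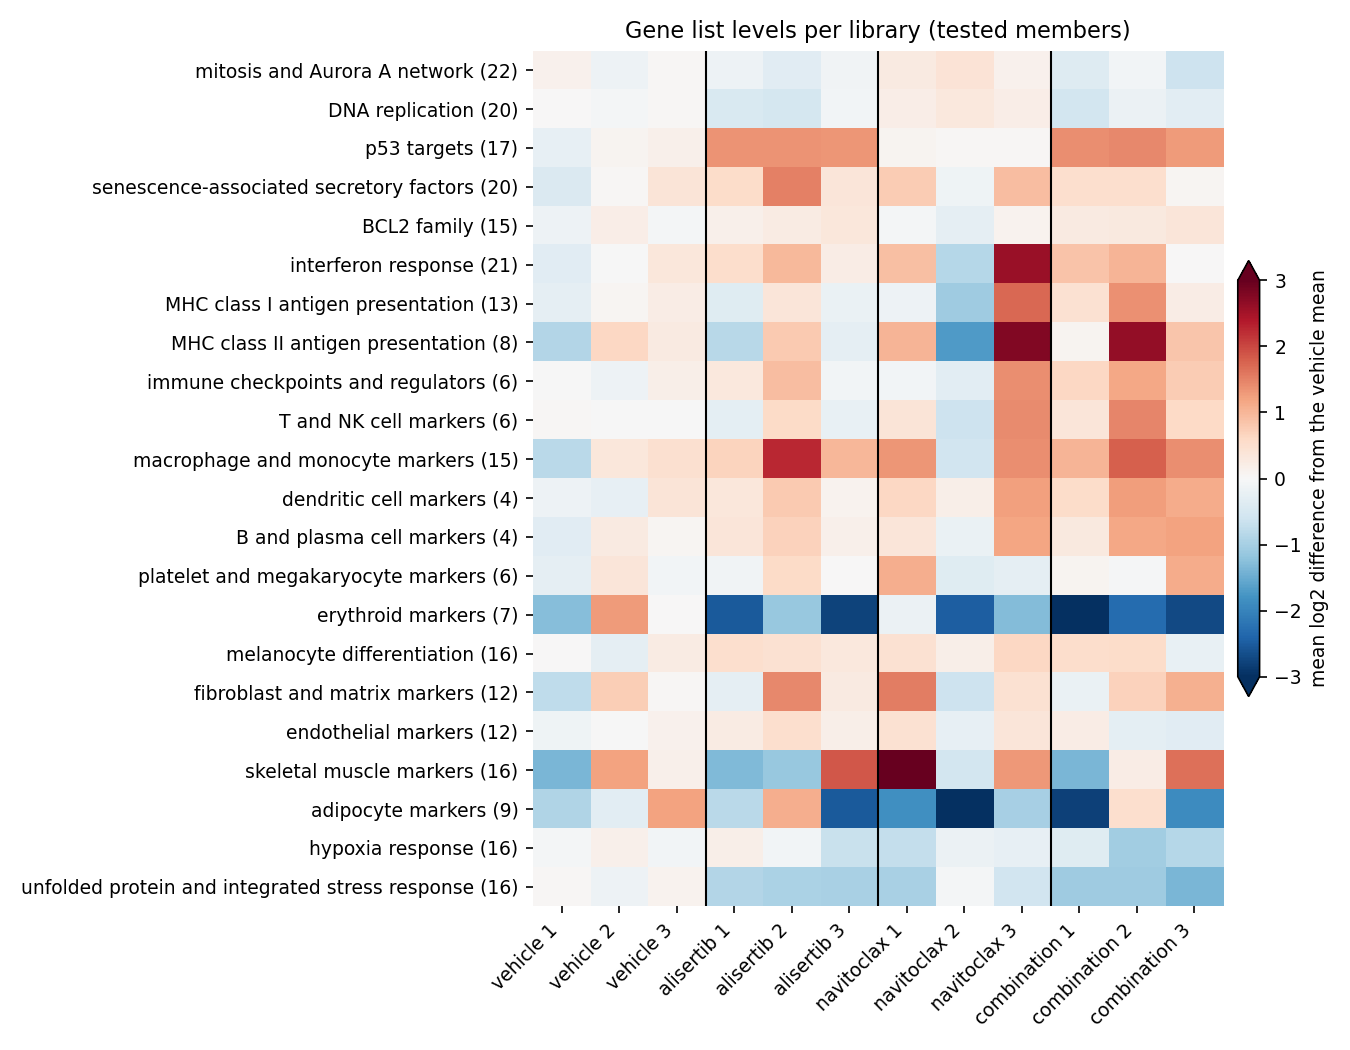
Mean log2 difference from the vehicle mean of each of the 22 tested lists in each library, on a scale from −3 to 3. The p53 list is higher in each library given alisertib, and the muscle list stands out in navitoclax 1.

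The main effects ask what each drug does on average with and without the other. For alisertib 765 genes passed, 445 higher and 320 lower. The proliferation marker Mki67 (ENSMUSG00000031004.8, chr7:135689784-135716361, minus strand) fell by 0.63 ± 0.11 (adjusted p = 0.0118). Its level was 10126 ± 950 with vehicle, 7081 ± 719 with alisertib and 6494 ± 1028 with both (n = 3 each). Top2a fell by 0.71 ± 0.14 (adjusted p = 0.0206) and Cenpf, a kinetochore protein, by 0.61 ± 0.13 (adjusted p = 0.0268). Mcm5 fell by 0.61 ± 0.10 (adjusted p = 0.00648) and Pole, a DNA polymerase, by 0.63 ± 0.11 (adjusted p = 0.0118). Cdkn1a rose by 1.59 ± 0.14 (adjusted p = 0.000178) and Zmat3 by 1.32 ± 0.09 (adjusted p = 5.53e-05). Bcl2l1 rose by 0.91 ± 0.14 (adjusted p = 0.00469), Bax by 0.79 ± 0.11 (adjusted p = 0.00352) and Bbc3 by 1.21 ± 0.22 (adjusted p = 0.0126). By the rule, the largest rises were of Svop (3.94 ± 0.26), Plcd4 (3.75 ± 0.52), Cpz (3.66 ± 0.22), Wfdc3 (adjusted p = 0.00994) and Timp4 (2.91 ± 0.52). By the rule, the largest falls were of Fgf21 (−4.56 ± 0.43), P2rx3 (−4.05 ± 0.46), Cdsn (−3.67 ± 0.48), Sspo (−2.80 ± 0.29) and Chac1 (−2.54 ± 0.29). For navitoclax 0 genes passed in limma, with 669 at an unadjusted p under 0.05, 0 in edgeR and 28 each in DESeq2 and with quality weights. The smallest p belonged to Sspo (−2.10 ± 0.29), Abca4 (−1.64 ± 0.27) and Tenm4 (−1.51 ± 0.25), each with adjusted p = 0.194. Avil (−1.26 ± 0.22, adjusted p = 0.239) and Kdelr3 (−0.92 ± 0.16, adjusted p = 0.244) did not pass either.

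For alisertib 10 lists passed. The p53 targets ranked higher, with 14 of 17 risen, 0 fallen and 17 positive (1.25, adjusted p = 2.11e-25, and 0.000645 with an estimated correlation). Mitosis ranked lower, with 5 of 22 fallen and 0 risen (−0.42, adjusted p = 1.1e-09, but adjusted p = 0.207 with an estimated correlation). In DNA replication 7 of 20 fell and 0 rose (−0.45, adjusted p = 1.11e-10, but adjusted p = 0.145 with an estimated correlation). In the stress response 7 of 16 fell and Sesn2 rose (−0.75, adjusted p = 2.67e-08, but adjusted p = 0.114 with an estimated correlation). In the BCL2 family 3 of 15 rose, of which Bax and Bbc3 are also in the p53 list (0.19, adjusted p = 0.00295, but adjusted p = 0.114 with an estimated correlation). Macrophage genes ranked higher, with 2 of 15 risen (1.29, adjusted p = 4.15e-05, but adjusted p = 0.47 with an estimated correlation). These were Mrc1, the mannose receptor (1.61 ± 0.37, adjusted p = 0.0338), and Ms4a7 (1.56 ± 0.36, adjusted p = 0.0367). No member passed in 4 lists. Melanocyte genes ranked higher (0.25, adjusted p = 0.0146, but adjusted p = 0.719 with an estimated correlation). Erythroid genes ranked lower (−1.97, adjusted p = 9.02e-05, but adjusted p = 0.306 with an estimated correlation). So did skeletal muscle (−1.65, adjusted p = 0.0268, but adjusted p = 0.765 with an estimated correlation) and hypoxia genes (−0.34, adjusted p = 0.00335, but adjusted p = 0.719 with an estimated correlation).

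For navitoclax 15 lists passed with no member passing. Hypoxia ranked lower (−0.46, 0 of 16 positive, adjusted p = 7.87e-13), as did the stress response (−0.33, adjusted p = 1.76e-07), both with adjusted p = 0.269 with an estimated correlation. Erythroid (−1.05, adjusted p = 3.6e-05, but adjusted p = 0.298 with an estimated correlation) and adipocyte genes (−1.24, adjusted p = 0.000107) ranked lower as well. MHC class I (0.46, adjusted p = 0.000742) and II (0.97, adjusted p = 0.000186), immune checkpoints (0.55, adjusted p = 0.0284) and T and NK cells (0.39, adjusted p = 0.00408) ranked higher. So did macrophages (0.49, adjusted p = 0.000683), muscle (1.67, adjusted p = 2.84e-05), melanocyte differentiation (0.14, adjusted p = 0.000742) and DNA replication (0.13, adjusted p = 0.000352). For these 8 lists and for adipocyte genes, adjusted p = 0.36 with an estimated correlation. Interferon response (0.43, adjusted p = 9.64e-05, but adjusted p = 0.416 with an estimated correlation) ranked higher. So did dendritic cell (0.57, adjusted p = 0.0137, but adjusted p = 0.269 with an estimated correlation) and B cell genes (0.60, adjusted p = 0.0383, but adjusted p = 0.298 with an estimated correlation).

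The 765 genes for alisertib became 336 without vehicle 1, 314 and 320 without alisertib 1 and 2, 433 and 419 without navitoclax 1 and 2 and 356 without combination 1. They were 1622 with DESeq2, 3028 with quality weights, 2731 with the covariate and 1494 without the 2 libraries rich in ribosomal RNA. The balance of 445 higher and 320 lower turned with the covariate (1291 and 1440), and was 782 and 712 without the 2 libraries. By adjusted p, Top2a and Cenpf were lost without vehicle 1, alisertib 1 or 2, navitoclax 1 or 2 or combination 1 (up to 0.0653 and 0.077). Mrc1 was lost without each but vehicle 2 and 3 and navitoclax 1 (up to 0.0933), and Ms4a7 without each but vehicle 3, navitoclax 3 and combination 1 (up to 0.0986). Melanocyte genes were lost without vehicle 2 (0.129) or combination 1 (0.083) or 2 (0.106), and hypoxia without alisertib 3 (0.0512). Muscle was lost without vehicle 2, alisertib 1 or 2, navitoclax 1 or combination 1 or 2 (0.0655 to 0.706). For navitoclax, interferon response (0.462) and MHC class I (0.333) were lost without navitoclax 3. Checkpoints were lost without vehicle 2 (0.0668), alisertib 3 (0.157), navitoclax 3 (0.333) or combination 2 (0.0888), and T and NK cells without navitoclax 3 (0.0549) or combination 2 (0.0552). Dendritic cells were lost without combination 3 (0.133), melanocyte genes without vehicle 2 (0.0604) and muscle without navitoclax 1 (0.367). B cells were lost without any vehicle library, alisertib 3, navitoclax 3 or combination 3 (0.0571 to 0.173).

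The interaction asks whether the effect of alisertib differs with navitoclax present. Avil passed alone (4.21 ± 0.45, adjusted p = 0.0198), with 1449 genes at an unadjusted p under 0.05. It stood at 319 ± 48.0 with vehicle, 24.3 ± 1.30 with alisertib, 30.5 ± 12.8 with navitoclax and 46.3 ± 13.5 with both (n = 3 each). The falls with each drug thus did not add. The vehicle mean enters this contrast with a positive sign, so chance high values of the shared vehicle libraries may account for a part. Sspo (4.24 ± 0.58, adjusted p = 0.12) and Col20a1, a collagen (1.29 ± 0.23), did not pass, nor did Abca4 (2.87 ± 0.54) or Plekha6 (2.35 ± 0.45, adjusted p = 0.436 for these 3). Of the lists, 6 ranked lower with no member passing, and for each adjusted p = 0.86 with an estimated correlation. They were mitosis (−0.43, adjusted p = 0.00378), secretory factors (−1.04, adjusted p = 0.0466) and interferon response (−0.65, adjusted p = 0.0466). Melanocyte differentiation (−0.48, adjusted p = 0.0273), endothelial (−0.42, adjusted p = 0.0448) and muscle genes (−2.46, adjusted p = 0.0466) were the others. Bub1b was at −0.54 ± 0.19 and Ccl2, a chemokine, at −3.08 ± 1.05. The p53 list did not pass (0.15, adjusted p = 0.448).

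Avil was lost, leaving 0 genes, without vehicle 1, 2 or 3 (adjusted p = 0.133, 0.0703, 0.0984) or alisertib 1, 2 or 3 (0.108, 0.117, 0.112). The same held without navitoclax 1 (0.0597) or combination 1 (0.0923). The 6 lists became 1 without vehicle 1, 2 without vehicle 3, navitoclax 1 or combination 2, 3 without navitoclax 3 or combination 1, and 10 without vehicle 2 or combination 3. Mitosis was kept without each library. Melanocyte differentiation was lost without vehicle 1 (0.0766) or navitoclax 3 (0.0705), and muscle without vehicle 1 or 3, alisertib 3, navitoclax 1 or combination 1 or 2 (up to 0.94). Endothelial genes were lost without vehicle 1 or 3, alisertib 2, navitoclax 1 or 3 or combination 2 (up to 0.203). Secretory factors were lost without any of these or combination 1 (up to 0.224), and interferon response without any of these, combination 1 or combination 3 (up to 0.777). Without navitoclax 3 the interferon list also turned to higher (0.777), and it passed as lower in 7 of 20 alternatives.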

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

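In this part, the tests chosen only after the result was seen were the correlation of the deviations of vehicle 2 and combination 3, with and without a GC trend, and the fit without both libraries. The effect of alisertib differed with and without navitoclax, by the test of the interaction itself, for 1 gene and 6 lists. Avil had an interaction of 4.21, with 319 ± 48.0 in vehicle tumours (n = 3) and at most 61.5 in each of the 9 treated libraries, which is a fall in each treated arm that did not add. The vehicle mean enters the interaction with a positive sign. Chance high values of the 3 shared vehicle libraries may thus account for a part of it, which stays open. The mitosis list had an interaction of −0.43. The senescence-associated secretory list had −1.04. The interferon response list had −0.65. The melanocyte differentiation list had −0.48. The endothelial list had −0.42. The skeletal muscle list had −2.46, with the muscle genes highest in navitoclax 1. None of these lists passed with an estimated correlation. Of 100 splits of the 12 libraries, 3 gave at least the 1 gene of the real split, which is 1 of these 3. These splits also break up the main effect of alisertib, so they test for no effect of any kind and do not exclude chance for the interaction. Another of them called 871 genes, with vehicle 2, alisertib 3 and combination 3 in 1 group. These libraries had the largest shares of reads at the ribosomal loci (63.3%, 35.4% and 73.7%), followed by combination 1 (26.6%). This points to a structure of the samples along that share. The fit without vehicle 2 and combination 3 still holds alisertib 3. For the 6 lists, 69 of 100 splits gave as many (highest 18), so chance cannot be excluded there either.

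Vehicle 2 and combination 3, which hold the most ribosomal RNA, deviated from their groups in the same genes. Low read depth alone was argued against, since the deviations correlated at 0.921 over 9998 genes with at least 200 mean reads, against −0.263 to 0.440 for pairs of an alisertib and a navitoclax library. A GC bias may account for a part: the deviation rose with transcript GC content (Spearman rho at least 0.436 in both), with medians from −0.48 to 0.44 in vehicle 2 and from −0.55 to 0.53 in combination 3 across 5 classes of GC content. It did not account for the whole, as the correlation was 0.904 after a GC trend was removed, and transcript length showed little relation (rho −0.0631). The labels give no batch and put these libraries in different groups, so the source of the rest stays open and no biological explanation was tested.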

How the results depend on the processing

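In this part, the settings chosen only after the results were seen were the TMM runs, pseudocounts of 0.5 and 8, the fit without the 2 libraries rich in ribosomal RNA and the ribosomal share as a covariate. Counts are given in the order alisertib, navitoclax, combination against vehicle, combination against navitoclax, interaction, and main effects of alisertib and of navitoclax; where fewer are given they are named. The reported counts were 148, 11, 431, 202, 1, 765 and 0, and edgeR with TMM gave 139, 10, 344, 185, 1, 747 and 0. DESeq2 gave 625, 76, 1184, 1008, 5, 1622 and 28, and voom with quality weights 1224, 37, 2104, 1623, 3, 3028 and 28. In the simulation, the navitoclax comparison had no gene changed, and only DESeq2 made calls there (23). In the simulated alisertib comparison, DESeq2 made 39 false calls among 160 and voom 2 among 87. No simulated library deviated as a whole, unlike vehicle 2 and combination 3, whose quality weights were 0.245 and 0.226. The simulation therefore does not tell how many of the larger counts in the data are false, with voom or any other tool. The cause of the larger counts was not tested. Only the compared groups in the fit, which leaves fewer libraries, gave 90, 0, 66 and 13 for the first 4. The covariate gave 770 for alisertib, 2028 for the combination, 630 against navitoclax, 2731 for the main effect of alisertib and 2 for that of navitoclax. Without the 2 rich libraries the combination against navitoclax gave 358, the interaction 0 and the main effect of alisertib 1494. No filter gave 117 for the combination against navitoclax, and CPM of at least 1 gave 4 for navitoclax. A pseudocount of 0.5 gave 3 and one of 8 gave 21 for navitoclax, and 8 gave 3 for the interaction and 1 for the main effect of navitoclax. The cause was not tested for any of these settings, the fits with fewer libraries included. The combination against alisertib gave 0 genes under each alternative.

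With 1 library left out, gene counts ranged from 49 to 198 (alisertib), 2 to 20 (navitoclax), 111 to 385 (combination), 0 to 0 (combination against alisertib), 53 to 293 (combination against navitoclax), 0 to 1 (interaction), 314 to 763 (alisertib main effect) and 0 to 0 (navitoclax main effect). For lists the order is alisertib, navitoclax, combination, combination against alisertib and against navitoclax, interaction, and both main effects. They ranged from 6 to 11, 7 to 15, 9 to 13, 2 to 9, 6 to 13, 1 to 10, 8 to 14 and 11 to 16. Reported lists numbered 9, 10, 10, 5, 9, 6, 10 and 15 in this order. With an estimated correlation they were 1, 0, 1, 0, 1, 0, 1 and 0, the p53 targets each time, and with fry 2, 0, 4, 0, 4, 0, 6 and 0. For the interaction, the CPM filter and limma on TMM-scaled values gave 3 lists each. The p53 targets were past the threshold and higher in 20 of 20 alternatives in each of the 4 contrasts that called them.

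Of the genes taken by size of change, 13 of 16 kept their call in each alternative for alisertib, 0 of 6 for navitoclax, 10 of 16 for the combination, 2 of 10 (Svop and Cpz) against navitoclax, 0 of 1 for the interaction and 10 of 10 for the main effect of alisertib, and 0 reversed. Only the compared groups in the fit ended the calls of Cdkn1a (adjusted p = 0.0586), Ccng1 (0.0543), Aen (0.0853) and Hspa5 (0.0586) in the combination, and of Sspo and Avil in navitoclax (up to 0.0871). No paired analysis was possible because the labels carry no replicate numbers. Depth limits genes in vehicle 2 and combination 3, where a value of 3 reads was 7.35 and 10.9.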

Other observations

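In this part, the tests chosen only after the result was seen were the p53 list without the 2 libraries rich in ribosomal RNA and the count of genes in which all vehicle libraries lay above all treated ones. Genes of skeletal muscle were abundant in 1 tumour: in navitoclax 1 the list stood 7.96 above the vehicle mean, and 16 of 16 muscle genes were highest there. Acta1, the actin of skeletal muscle, was at 62.7 ± 60.7 with vehicle and 7164 ± 12282 with navitoclax (n = 3 each). Immune genes varied between tumours of 1 group. Navitoclax 3 had the highest level of interferon response (2.60), MHC class I (1.73) and MHC class II genes (2.79), and navitoclax 2 the lowest (−0.86, −1.07, −1.69). Combination 2 stood at 1.01, 1.36 and 2.63, with the highest level of T and NK cell markers (1.46).

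In the main effect of alisertib, members of lists that did not pass also changed. Lck, a kinase of T cells, fell by 1.10 ± 0.20 (adjusted p = 0.0135; 49.3 ± 4.92 with vehicle, 19.4 ± 3.55 with alisertib). Il1b, a cytokine, fell by 1.95 ± 0.48 (adjusted p = 0.0441) from few reads, and Cd22 rose by 1.76 ± 0.33 (adjusted p = 0.0149). Il1b was lost without any vehicle or alisertib library, navitoclax 1 or 3 or combination 1 or 3 (up to 0.111), and Cd22 without alisertib 2 (0.0506). Over all tested genes, 392 had all vehicle libraries above all treated ones and 177 below, where chance gives 77.2 (0.455%) each on average. Genes vary together and no other choice of 3 libraries was counted. The spread around 77.2 is therefore unknown, and these counts do not exclude chance.

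The p53 target genes were higher in each library given alisertib. The mean level of the list was 1.34 ± 0.01 with alisertib (1.33 to 1.35), 1.37 ± 0.08 with both drugs (1.28 to 1.44) and 0.05 ± 0.02 with navitoclax (0.03 to 0.07). Without the 2 libraries rich in ribosomal RNA the median of the alisertib main effect was 1.27 (17 of 17 positive, adjusted p = 0.0277 with an estimated correlation), which argues against those libraries as the source. With the macrophage list as a covariate it was 1.31 (16 of 17 positive, adjusted p = 0.00139 with an estimated correlation). Navitoclax 1 and 3 had macrophage levels of 1.33 and 1.39, within the range of the alisertib libraries. Their p53 levels were 0.07 and 0.04. This also argues against a larger amount of macrophage RNA as the source, but not against a response to alisertib within macrophages. A response of the tumour cells to alisertib remains a hypothesis that the medians of 1.27 and 1.31 leave open. These checks do not tell tumour cells from other cells of the tumour, and the pattern was found and tested on the same data.

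The 11 genes lower with navitoclax were, beside those named, Otog (−4.65, adjusted p = 0.0218; 235 ± 27.1 with vehicle), Trim66 (−3.12), 4930438A08Rik, H2-M10.1 and Ppef1, chosen after their values were seen. In 10 of 11, all but Plekha6, each of the 3 vehicle libraries lay above each of the 9 treated libraries, in part because the call selects for this; the lowest vehicle and highest treated values were 203 and 12.7 for Otog, 804 and 71.2 for Sspo and 291 and 61.5 for Avil, which argues against a single vehicle library. The same 10 were also called lower with alisertib and with both drugs, where independent sets would share 0.0350 and 0.127, and 100 simulations with shared vehicle libraries alone at most 0. These contrasts share the vehicle libraries: fold changes of navitoclax and the combination correlated at 0.45, below the 0.51 (0.48 to 0.54) of simulations with that sharing alone, with a covariance of 0.157 above the simulated 0.0998, and those of alisertib and navitoclax at 0.71 against 0.53. The simulated genes held no effect and varied independently, so their overlap of 0 and their correlations leave out structure shared across genes. Chance values of the shared vehicle libraries may still account for a part of the 10. This stays open, since 3 vehicle libraries cannot be split.

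The compared libraries can be split into groups of 3 in 10 ways, the real one included, too few for a share under 0.05. The real split and the highest other gave 148 and 0 genes for alisertib, 11 and 0 for navitoclax, 431 and 0 for the combination and 202 and 1 for the combination against navitoclax (1 of 10 as large each, the real split itself). For the combination against alisertib they gave 0 and 0 (10 of 10). For lists they gave 9 and 12 (3 of 10), 10 and 14 (5 of 10), 10 and 11 (2 of 10), 9 and 14 (6 of 10) and 5 and 15 (6 of 10) in the same order. For the main effect of alisertib, 100 splits moved libraries only within the tumours without navitoclax and within those with it. Of these, 1 gave as many genes as the 765 reported (the real split itself, highest other 13). This argues against chance for that count, as a test against no effect of alisertib with or without navitoclax, if the libraries are independent samples. The labels do not say that they are. For navitoclax the splits kept alisertib given or not in the same way. As many as the 0 of navitoclax came in 100 of 100 (highest other 1). For lists, 51 of 100 gave as many as the 10 of alisertib (highest other 18) and 7 of 100 as many as the 15 of navitoclax (highest other 16), so chance cannot be excluded there.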
